A study of Mus musculus with 3 samples.

How the data were processed

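Hardy fraction A-B cells of mouse bone marrow were sequenced as 3 bulk libraries of total RNA, 1 each for the genotypes WT, IkB- and IkB-/cRel-, per the labels. Lymphoid progenitors were enriched magnetically and sorted by flow cytometry, and the labels name a C57BL/6J and an IkB- mouse and numbered staining panels without their markers, per the labels' protocols. About 204000 cells were sorted for WT and for IkB-, and 10 ng of yeast RNA was added per 100000 cells, per the labels' protocols. The series title, labels and design text were the only description of the study used. The genotypes were taken from the genotype labels of the samples.

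The authors deposited 1 table of counts and 1 table of normalized signal, each with the 3 libraries as columns. The deposited counts are fragments per gene, made by the authors with featureCounts 1.6.5 on paired reads with reverse strandedness (setting 2), exons summed by gene, per the file headers. Before counting, reads were trimmed with cutadapt 4.1 and aligned with STAR 2.7.1a to the joined mouse GRCm39 and yeast R64 genomes, per the series design text. STAR ran with the BySJout filter, up to 20 multiple hits, splice overhangs of at least 8 and 1, and a seed search start of 30, and SAMtools 1.9 kept alignments of mapping quality 30 or more, per the same text. The deposited signal is the mouse gene counts divided by all yeast gene counts of the library and multiplied by 1000000 by the authors, per the series design text. This was checked by dividing the deposited counts by the deposited signal, which gave 1 constant per library, equal to its yeast total divided by 1000000, to within a relative deviation of 4.95e-07. No per-sample column was left unused.

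The libraries held 25612217, 44814325 and 9351681 mouse counts, so that the count of 3 used as a floor stood for 0.117, 0.0669 and 0.321 CPM (counts divided by all mouse counts of the library and multiplied by 1000000) in WT, IkB- and IkB-/cRel-. Mouse gene identifiers were matched to GENCODE M39 for symbols, biotypes and GRCm39 coordinates (56236 matched, 744 not). Of the mouse genes, 12716 with at least 100 counts summed over the 3 libraries were compared, 11258 of them protein coding. A count of 0 was replaced by 3 and the fold given as a bound (59 genes had a 0 in some library), and no fold was computed where both counts were 3 or less, a rule added after a first run, which made the set of the second pattern in the closing section smaller. Tests of neighbouring genes were written for further patterns and left out without being run, because no more than 3 patterns were weighed.

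The comparisons were IkB- over WT, IkB-/cRel- over WT and IkB-/cRel- over IkB-. With 1 library per genotype no test was made. Each gene has 2 log2 ratios. The yeast scale is the authors' own, with mouse counts divided by the total of yeast counts. The ratio relative to the median gene subtracts the median log2 ratio of all compared genes, and does not depend on the yeast RNA. Intervals are 95% conditional binomial (Clopper-Pearson) intervals, and those of the folds of mouse counts per yeast count are normal intervals of the log fold. For 43 gene lists (1096 of 1168 members compared) the median log2 ratio was placed among 10000 random lists of the same size matched on mean count in 20 bins (seed 1), and members at least 1.5-fold from the median gene were counted. The rank describes these libraries and is not a test. Random lists draw genes singly, while members of a list can vary together between preparations. Genes at least 2-fold apart between IkB- and WT were followed into IkB-/cRel-, as the share nearer to WT and the median percent of the log2 difference kept. The overlap of the 2 comparisons with WT was set beside the number 2 independent lists would share and the mean over 20 simulations of libraries with no difference, a step added after the data were seen.

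The lists, comparisons, thresholds, alternatives and the rule for naming genes were fixed before the data were examined. The rule names all NFkB family members. It then names per comparison the 8 protein-coding genes highest and 8 lowest by the interval bound nearest 0, without immunoglobulin and T cell receptor genes. For each list described it names up to 4 members with the largest bound and up to 4 with the highest counts, and for each marker list of another cell type the member with the highest count. A gene named in 1 comparison could be given in the others, which is how Cd40 came to be given for IkB-/cRel- over WT. The immunoglobulin, mt-Nd3 and Ifi200 cluster values given in the closing section and the genes named in the tests of the closing section were chosen after their values were seen. In the tests on pro-B identity genes of the closing section 1 further gene is not reported here and was taken out of the computation after a first run, which left the gap to Rag1 and Rag2 and the widest range as they were.

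The alternatives were other totals for the mouse per yeast ratio, scaling by total mouse counts, by edgeR TMM factors and by DESeq2 size factors, count minimums of 30 and 1000, the whole interval beyond 2-fold, a pseudocount of 10, the mean in place of the median over list members, the yeast scale, and selection at 1.5-fold or on thinned counts. edgeR 4.0.16 and DESeq2 1.42.0 under R 4.3.3 were used for scaling factors only. All other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

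The steps were tested on simulated data, with counts drawn for 12716 genes from the real means and library sizes, 100 genes changed by a log2 of 1.5 and 100 by 3. At 2-fold, 100% of both sizes were recovered for IkB- over WT and for IkB-/cRel- over WT, and 99% and 100% for IkB-/cRel- over IkB-. Of 12516 unchanged genes, 0, 37 and 28 passed 2-fold in the 3 comparisons, and the intervals held the true value for 95.1%, 95.6% and 95.6% of them. The simulated counts were Poisson draws with no spread between animals or preparations. They check the computation and give no error rate for the real libraries.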

Results

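Total RNA of Hardy fraction A-B cells was sequenced in 3 libraries, 1 per genotype, labelled WT, IkB- and IkB-/cRel-. Hardy fractions A and B are the earliest B-lineage stages of mouse bone marrow, before the pre-B cell stage. IkB proteins hold NFkB transcription factors inactive in the cytoplasm, and cRel, the product of Rel, is an NFkB subunit. The series title places the 3 genotypes in a study of how NFkB activity bears on protein homeostasis, proliferation and differentiation during B cell development. WT and IkB- were each stated to hold about 204000 sorted cells, and no number was stated for IkB-/cRel-. Yeast RNA was added at 10 ng per 100000 cells, so that mouse counts can be read per yeast count. Mouse genes held 25612217 counts in WT, 44814325 in IkB- and 9351681 in IkB-/cRel-, and yeast genes held 111106062, 81881733 and 134277880. With 1 library per genotype, no difference has a replicate check, no test was made and no p-value is given. The 95% intervals given after values cover counting error only, as 1 library per genotype shows no spread between preparations. They take reads as independent molecules, which PCR reads without molecular identifiers are not, so they may be too narrow.

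The first question was how much mouse RNA each library held per unit of added yeast RNA. Mouse genes took 18.7% of all counts in WT, 35.4% in IkB- and 6.51% in IkB-/cRel-. Mouse counts per yeast count were 0.231 in WT (0.2304 to 0.2306), 0.547 in IkB- (0.5471 to 0.5475) and 0.0696 in IkB-/cRel- (0.06960 to 0.06969). The IkB- library was 2.37-fold above WT (2.373 to 2.376), and the IkB-/cRel- library was 3.31-fold below WT (3.307 to 3.313) and 7.86-fold below IkB- (7.853 to 7.865). The median mouse gene moved by about as much, with a log2 ratio on the yeast scale of 1.30 for IkB- over WT, -1.67 for IkB-/cRel- over WT and -2.96 for IkB-/cRel- over IkB-. On that scale 8698 genes were at least 2-fold higher and 211 at least 2-fold lower in IkB- than in WT, among 12715 genes with a ratio. For IkB-/cRel- over WT the numbers were 115 higher and 10617 lower, and for IkB-/cRel- over IkB- 40 higher and 12580 lower. Each genotype had 1 library, so a difference in RNA per cell and a difference in cells or yeast RNA per library give the same ratio. All values below are therefore given relative to the median gene unless the yeast scale is named. On this second scale, 1559 genes were at least 2-fold higher and 1013 lower for IkB- over WT, 1224 and 843 for IkB-/cRel- over WT, and 415 and 627 for IkB-/cRel- over IkB-. These numbers depend on the count minimum and on counting error: at a minimum of 1000 counts they were 797 and 366, 591 and 278, and 79 and 163, and with the whole interval beyond 2-fold 669 genes were lower in IkB- and 713 higher and 351 lower in IkB-/cRel- than in WT.

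**Figure D1:**
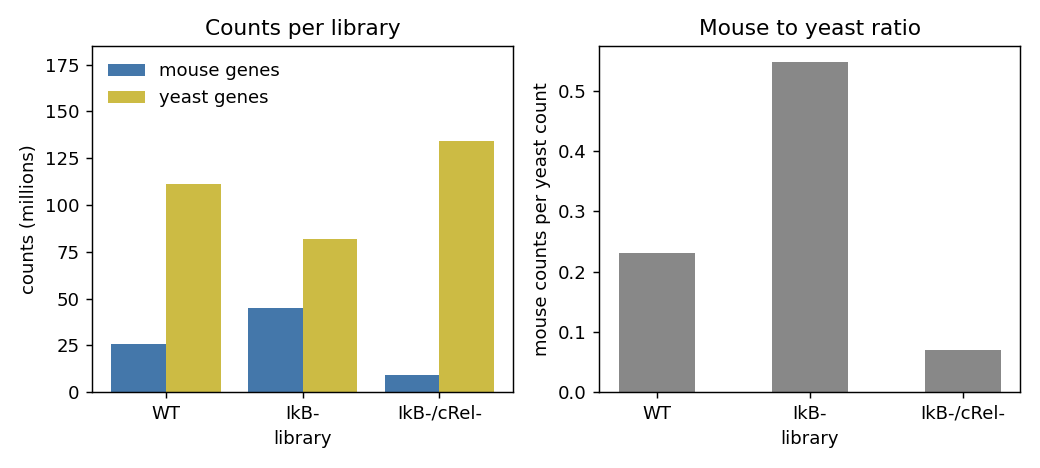
Counts of the 3 libraries. The left panel shows bars of the summed counts at mouse and at yeast genes and the right panel the mouse counts per yeast count, which were 0.231 in WT, 0.547 in IkB- and 0.0696 in IkB-/cRel-.

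The genes of the NFkB family and its inhibitors were examined in every library before other genes. Nfkbie, the gene of the inhibitor IkB epsilon (GRCm39 chromosome 17, 45866629 to 45874095), had 1820 counts in WT, 103 in IkB- and 44 in IkB-/cRel-. Its log2 ratio was -5.00 (-5.30 to -4.71) for IkB- over WT and -3.97 (-4.44 to -3.54) for IkB-/cRel- over WT. Nfkbib, the gene of IkB beta (chromosome 7, 28457676 to 28466937), was lower by less, with -1.19 (-1.36 to -1.02) in IkB-, where the yeast scale gave 0.10, and -1.34 (-1.67 to -1.03) in IkB-/cRel-. Nfkbia, the gene of IkB alpha (chromosome 12, 55536195 to 55539432), was at 0.67 (0.60 to 0.75) and 0.37 (0.26 to 0.49) over WT. Rel (chromosome 11, 23686847 to 23720970) had 1826, 3974 and 410 counts in WT, IkB- and IkB-/cRel-, which was 0.27 (0.19 to 0.35) for IkB- over WT and -0.76 (-0.92 to -0.60) for IkB-/cRel- over WT. Counts at Rel were thus lower but present in the library labelled IkB-/cRel-, and as the labels do not say which part of Rel was removed or which IkB genes were targeted, gene totals check the labels only in part. Among the other members, the gene of the atypical IkB protein Bcl3 was at 3.31 (3.10 to 3.53) in IkB- and 1.90 (1.62 to 2.18) in IkB-/cRel- over WT. Nfkb2, which encodes p100, was at 2.14 (2.03 to 2.25) and 1.34 (1.19 to 1.48), the latter turning to -0.33 on the yeast scale, and Relb was at 1.92 (1.75 to 2.10) and 1.77 (1.55 to 1.99). Nfkb1, which encodes p105, was at 1.17 and 0.89, Rela at 0.68 and 0.55, Nfkbiz at 0.98 and 0.60, and Nfkbid at 0.66 and 0.33. The kinase subunit genes Chuk, Ikbkb and Ikbkg lay between 0.38 and 0.71 in IkB- and between 0.33 and 0.64 in IkB-/cRel-. The median over the 14 genes was 0.67 in IkB-, above 9998 of 10000 random lists of the same size and mean count, and 0.55 in IkB-/cRel-, above 9996, with 1.97 and -1.12 on the yeast scale. All members other than Nfkbie and Ikbkg were lower in IkB-/cRel- than in IkB-, Bcl3 by the most, at -1.41 (-1.60 to -1.23).

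The IkB- library was set beside WT to ask what the IkB- label goes with in early B-lineage cells. Most NFkB target genes and most members of the later B cell list were higher relative to the median gene. The mature B cell markers Igkc, Ighd, Ms4a1 and Cd22, weighed in the closing section, had a median of -0.03 on the same measure. The lists of V(D)J recombination, mitosis, replication, chaperone and ribosomal protein genes had medians below 0 on this measure and above 0 on the yeast scale. Cd74, the invariant chain of class II antigen presentation, was 15.9-fold higher, at 3.99 (3.95 to 4.02), and H2-Aa, a class II chain, was at 3.62 (3.58 to 3.66). Cd40, the receptor for T cell help, was 17.3-fold higher, at 4.11 (3.80 to 4.44). Rag1 and Rag2, the recombinase that joins antigen receptor segments, were 5.39-fold and 5.97-fold lower, at -2.43 (-2.46 to -2.40) and -2.58 (-2.63 to -2.53), and were lower on the yeast scale too, at -1.14 and -1.28. The median gene itself was 2.45-fold higher per yeast count in this library, so list medians below 0 relative to it were in most cases above 0 on the yeast scale, as given with each list.

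The NFkB target genes had a median of 1.18 in IkB- over WT, above 10000 of 10000 random lists, and 20 of 31 measured members were at least 1.5-fold higher and 1 lower. Ebi3, a subunit of interleukin-27 and interleukin-35, was at 3.98, the adhesion molecule Vcam1 at 2.43 and lymphotoxin beta, Ltb, at 2.08. Among later B cell genes the median was 0.74, above 10000 random lists, with 22 of 35 members higher and 6 lower. The later B cell and NFkB target lists overlap, as Cd40, Cd83, Ltb, Ccr7 and Ebi3 are members of both. The low-affinity IgE receptor Fcer2a was at 4.79, H2-DMb2, which helps load class II molecules, at 4.79 and H2-Eb1 at 4.15, while the mu heavy chain Ighm was at -0.20. Of the mature B cell markers of the closing section, Igkc and Ms4a1 were higher in IkB- than in WT, and Ighd and Cd22 were lower. The higher median of the later B cell list was thus not shared by all B cell genes. V(D)J recombination genes had a median of -0.91, below all 10000 random lists (0.38 on the yeast scale), with 11 of 17 lower and 2 higher. Dntt, the terminal transferase that adds N nucleotides, was 2.84-fold lower and the Ku70 gene Xrcc6 at -1.65. For pro-B surface and pre-B cell receptor genes the median was -0.52 (0.78 on the yeast scale), with 9 of 25 lower and 5 higher. The surrogate light chain Igll1 was at -1.24, or 0.06 on the yeast scale, Cd24a at -1.64, or -0.35, and the surface antigen Ly6d at 1.92. B lineage transcription factors went both ways (8 of 30 higher, 10 lower). Ebf1, which specifies the B lineage, was at -1.56, Lef1 at -2.37 and Irf8 at 1.28, while Ikzf3 was 2.83-fold higher.

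Mitosis genes had a median of -0.83 in IkB- over WT (0.46 on the yeast scale), with 26 of 37 at least 1.5-fold lower and 0 higher, and DNA replication genes -0.61 (0.69), with 20 of 38 lower. The proliferation marker Mki67 was at -0.87, or 0.43 on the yeast scale, and the replication clamp Pcna at -1.04, or 0.26 on the yeast scale. Cytosolic chaperones had a median of -0.69 (0.60 on the yeast scale), below all 10000 random lists, with 23 of 40 lower. The constitutive Hsp70 gene Hspa8 was at -1.68 (-1.69 to -1.66), the Hsp90 gene Hsp90aa1 at -1.89 (-1.91 to -1.86) and Hsph1 at -2.50 (-2.56 to -2.43), and these were below 0 on the yeast scale too. Bag3, a co-chaperone of Hsp70, was the 1 member at least 1.5-fold higher, at 3.10 (2.62 to 3.62). Cytosolic ribosomal protein genes had a median of -0.65 (0.64 on the yeast scale), with 48 of 77 lower and none higher, for example Rps3 at -0.71. Mitochondrial ribosomal protein genes were at -0.40 (0.90). The 20S core of the proteasome, the protease that degrades ubiquitin-tagged proteins, had a median of -0.40 (0.89 on the yeast scale), below all but 111 of 10000 random lists, though only 3 of 14 members were at least 1.5-fold lower, and its 19S cap -0.24 (1.06), with 1 of 18 lower. Immunoproteasome genes had a median of 0.59 (1.88 on the yeast scale), above 9603 of 10000 random lists and so inside their middle 95%, with 3 of 5 higher and Psmb9 at 1.07. Chaperones of the endoplasmic reticulum and the unfolded protein response had a median of 0.33, above 9996 random lists, with 10 of 44 higher. Derl3 was at 2.59 and the stress sensor Ern1 at 1.47, while the abundant chaperones Hspa5 and Hsp90b1 were at -0.11 and -0.07. Dilution of pro-B RNA, weighed in the closing section, was not tested for the lists of this paragraph, here or in IkB-/cRel-.

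Markers of other cells also differed between IkB- and WT. Neutrophil markers had a median of 2.03, with all 12 measured members at least 1.5-fold higher, and S100a9 stood at 9.84 CPM (counts scaled to a mouse total of 1000000) in WT and 48.3 in IkB-. Erythroid markers were at 1.10 with 7 of 9 higher and 1 lower, and dendritic cell markers at 0.75 with 9 of 14 higher. Monocyte and macrophage markers were at 0.69 with 6 of 9 higher and 3 lower, among the latter F13a1 at -1.70 and Lyz2 at -0.86, and at a count minimum of 1000 the median turned to -0.069. Siglech, a receptor of plasmacytoid dendritic cells, was at 1.43 (1.41 to 1.45), from 825 CPM in WT. Plasma cell markers had a median of -2.13 (-0.84 on the yeast scale), with 6 of 8 lower and 2 higher. Igha was at -8.15 and Jchain at -3.72, and Derl3, among the higher ones, at 2.59. By the naming rule, the genes highest in IkB- were the interleukin-9 receptor Il9r at 9.13 (8.20 to 10.26), the adhesion molecules Clmp at 9.19 (7.33 to 12.23) and Cadm3 at 7.73 (7.09 to 8.46), the actin bundling protein Fscn1 at 7.26 (6.62 to 8.00) and the interferon-inducible GTPase Iigp1c at 7.18 (5.95 to 8.80). The predicted genes F830016B08Rik, at 8.43 (5.95 to 13.74), and Gm4841, at 7.76 (5.90 to 10.81), lie beside Iigp1c on chromosome 18. The kallikrein Klk1b22 had 0 counts in WT and was at least 77.2-fold higher in IkB-. Those lowest were Heyl, a transcription factor downstream of Notch, at -6.45 (-6.98 to -5.97), the cytokine Il33 at -7.15 (-9.43 to -5.58), the protease inhibitor Serpina3n at -6.19 (-8.08 to -4.80), Speer2 at -6.05 (-7.51 to -4.91) and Gm15446 at -5.63 (-6.56 to -4.84). Enpep, the BP-1 antigen that separates Hardy fraction C from fraction B, was at -5.25 (-5.77 to -4.78). Rbm44 and Gm14137 had 0 counts in IkB- and were at least 121-fold and at least 62.7-fold lower. The values of Klk1b22, Iigp1c, Gm4841, F830016B08Rik, Speer2, Gm15446 and Gm14137 are uncertain because these genes have near-identical copies. Reads that align to several copies could be lost at the mapping quality minimum of 30.

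**Figure D2:**
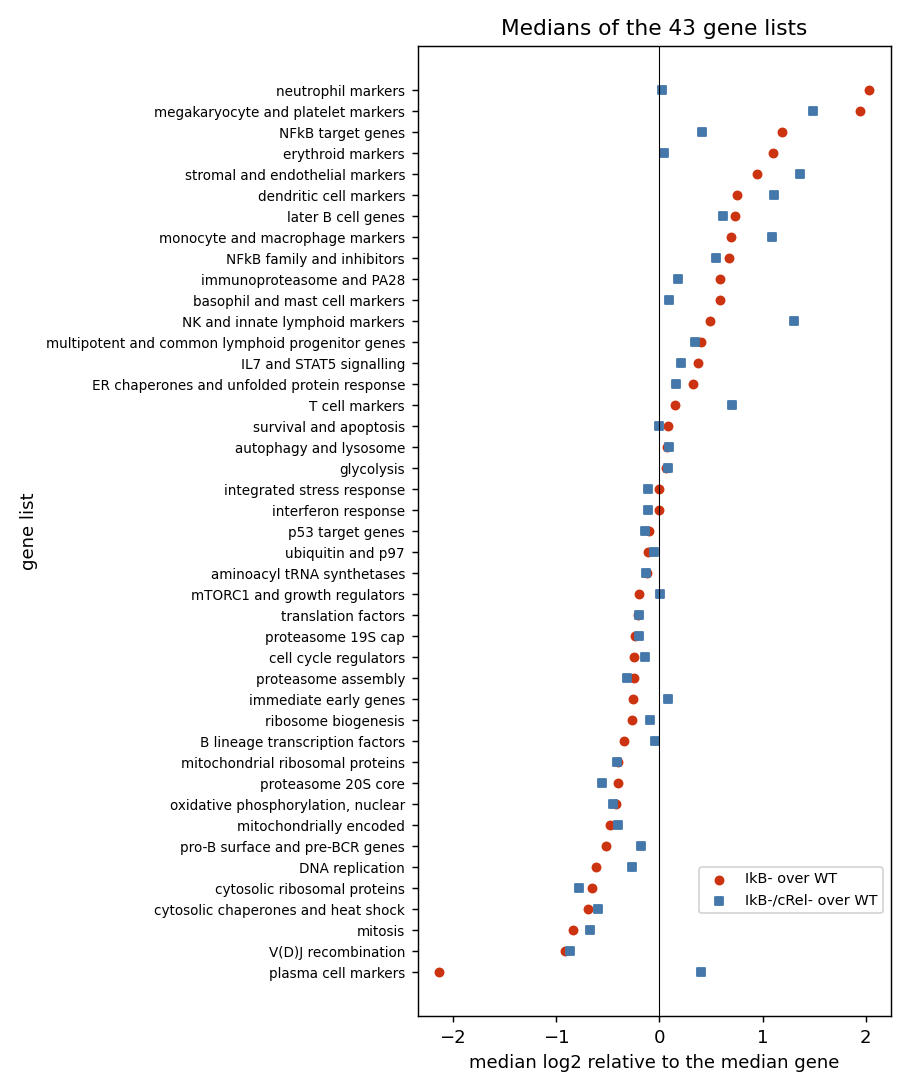
Median log2 ratio relative to the median gene of each of the 43 gene lists, with circles for IkB- over WT and squares for IkB-/cRel- over WT. V(D)J recombination (-0.91 and -0.86), mitosis, chaperone and ribosomal protein lists lie below 0 in both, though on the yeast scale these 4 lists are above 0 for IkB-, and neutrophil markers are at 2.03 and 0.03, the latter -1.64 on the yeast scale.

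The IkB-/cRel- library was set beside WT to ask how the combined genotype differs from WT. Many groups lay on the same side as in IkB-, though all lists had a median below 0 on the yeast scale, where the median gene was 3.18-fold lower. Rag1 was 3.62-fold and Rag2 5.17-fold lower, at -1.85 (-1.90 to -1.81) and -2.37 (-2.46 to -2.28), and V(D)J recombination genes had a median of -0.86, with 11 of 17 lower. Hspa8 was at -1.77 (-1.80 to -1.74). Cd74 was 6.93-fold higher, at 2.79 (2.75 to 2.83), while Cd40 was at 0.62 (0.08 to 1.15), or -1.05 on the yeast scale.

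NFkB target genes had a median of 0.41 (-1.26 on the yeast scale), above 9993 of 10000 random lists, with 14 of 31 higher and 2 lower relative to the median gene. The kinase Map3k8 was at 1.73, or 0.06 on the yeast scale, and the adhesion receptor Cd44 at 1.05, or -0.62. Later B cell genes were at 0.62 (-1.05 on the yeast scale), with 19 of 35 higher and 6 lower, H2-Eb1 at 2.51 and H2-Ab1 at 2.27. The pro-B and pre-B cell receptor list had a median of -0.18, inside the range of random lists (1488 of 10000 below it), with 9 of 25 lower and 5 higher. Igll1 was at -1.43, the signalling chain Cd79b at -1.47 and Vpreb3 at -1.36, while the adaptor Sh2b2 was at 1.90 and Ly6d at 0.88, or -0.79 on the yeast scale. Ebf1 was at -1.08. Irf8 was at 1.21, or -0.46 on the yeast scale. The medians of the ribosomal protein, chaperone, proteasome core, mitosis and replication lists were below 0 on both scales. Cytosolic ribosomal protein genes had a median of -0.78 (-2.45 on the yeast scale), with 61 of 77 lower and none higher, mitochondrial ribosomal protein genes -0.41, chaperones -0.59, the 20S core -0.56, below all but 2 random lists, mitosis genes -0.67 and replication genes -0.26. The stress-inducible Hsp70 genes Hspa1a and Hspa1b had 0 and 6 counts in IkB-/cRel-, so that Hspa1a was at least 7.34-fold lower and Hspa1b was at -3.44 (-4.91 to -2.29). Bag3 was at 2.66 (2.10 to 3.26). Immunoproteasome genes had a median of 0.18 (-1.49 on the yeast scale), with none of the 5 at least 1.5-fold apart from the median gene.

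Dendritic cell markers were at 1.11 in IkB-/cRel- over WT, with 11 of 14 higher, NK and innate lymphoid markers at 1.30 with 11 of 14 higher, and neutrophil markers at 0.03, while on the yeast scale these medians were -0.56, -0.37 and -1.64. Siglech was at 1.37 (1.34 to 1.39), or -0.30 on the yeast scale, and the interleukin-2 receptor chain Il2rb at 1.96 and Cd4 at 3.25. Of the genes named by size, Klk1b22 was at least 160-fold and Gfra3, a receptor for a glial growth factor, at least 19.3-fold higher against 0 counts in WT. Mansc4 was at 8.18 (5.67 to 13.49), the myosin heavy chain Myh13 at 5.82 (4.99 to 6.79), the adhesion molecule Cadm1 at 4.90 (4.72 to 5.09), the olfactory receptor Or10aa3 at 5.98 (4.58 to 7.89), the interferon-inducible p200 gene Ifi204 at 4.49 (3.96 to 5.05) and the kinase scaffold Mapk8ip1 at 5.79 (3.85 to 8.88). The lowest were the peptide transporter Slc15a2 at -5.31 (-5.94 to -4.75), Gm15446 at -6.08 (-9.13 to -4.22), Nfkbie, Speer2 at -5.38 (-8.44 to -3.51), Pcp4l1 at -3.20 (-3.57 to -2.85), Ifi213 at -3.89 (-5.22 to -2.83) and the kallikrein Klk1 at -3.01 (-3.41 to -2.63). AI661453 had 0 counts in IkB-/cRel- and was at least 12.4-fold lower. Klk1b22, Klk1, Or10aa3, Ifi204, Ifi213, Speer2 and Gm15446 have near-identical copies, so reads could be lost at the mapping quality minimum, which makes these values uncertain.

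The IkB-/cRel- library was then set beside IkB-, which asks what differs when the label holds cRel- in addition, counts at Rel being lower but present. Relative to the median gene the libraries were closer to each other than either was to WT, with 415 genes at least 2-fold higher and 627 lower in IkB-/cRel- (222 and 278 with the whole interval beyond 2-fold, 961 and 1289 at a count minimum of 30, 79 and 163 at 1000), and on the yeast scale all 43 lists had a median below 0. NFkB target genes were lower in IkB-/cRel-, with a median of -0.39 below all 10000 random lists, 13 of 31 lower and 2 higher. Cd40 was 11.2-fold lower, at -3.49 (-3.93 to -3.08), Vcam1 was at -3.42 (-5.31 to -2.04), Ebi3 at -2.83 (-3.22 to -2.46) and the death receptor Fas at -2.30 (-3.07 to -1.63). Later B cell genes had a median of -0.94, with 22 of 35 lower and 4 higher, Fcer2a at -3.72 (-4.43 to -3.08), Cd74 at -1.20 and H2-Aa at -1.55.

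Members of the interferon response list went both ways in IkB-/cRel- over IkB- (8 of 40 higher, 7 lower), the GTPases Gbp2 at -3.55 (-3.77 to -3.33) and Iigp1 at -3.25 (-3.46 to -3.04) among the lower ones. The immunoproteasome median was -0.42 and that of endoplasmic reticulum chaperones -0.16. Replication genes had a median of 0.28, mitosis genes 0.17 and ribosome biogenesis genes 0.17, each above all 10000 random lists, but at -2.68, -2.79 and -2.79 on the yeast scale. Few single members passed 1.5-fold (0, 0 and 1 in the 3 lists), with the DNA methylation reader Uhrf1 at 0.48. V(D)J recombination genes were at 0.03, chaperones at 0.04, the 20S core at -0.10 and the 19S cap at 0.04, and Rag1 was at 0.57, or -2.39 on the yeast scale. Neutrophil markers had a median of -1.81 and erythroid markers of -1.43, while NK and innate lymphoid markers were at 0.65, or -2.31 on the yeast scale. The highest genes were Or10aa3, at least 152-fold higher against 0 counts in IkB-, Ifi204 at 5.48 (4.93 to 6.07), the progesterone receptor Pgr at 5.75 (4.56 to 7.25), Heyl at 4.95 (4.43 to 5.50), Jchain, which joins IgA and IgM multimers, at 4.22 (4.04 to 4.40), Cadm1 at 3.57 (3.48 to 3.67), the NK cell receptor Klra8 at 4.33 (3.47 to 5.28) and Rbm44, at least 28.6-fold higher. Lowest were Il9r at -8.31 (-9.76 to -7.19), the autoimmune regulator Aire at -6.07 (-7.52 to -4.94), Gm4841 at -7.36 (-12.67 to -4.88), Cadm3 at -4.78 (-5.18 to -4.40), Sema6d at -5.82 (-8.10 to -4.27) and Fscn1 at -4.62 (-5.08 to -4.20). F830016B08Rik and the peptide hormone adrenomedullin, Adm, had 0 counts in IkB-/cRel- and were at least 43.8-fold and at least 19.3-fold lower. Reads of Or10aa3, Ifi204, Klra8, Gm4841 and F830016B08Rik that also align to near-identical copies could be lost, so these 5 values are uncertain.

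Of the genes at least 2-fold higher in IkB- than in WT that had a ratio in both comparisons, 1538 were followed into IkB-/cRel-. The IkB-/cRel- value lay nearer to WT than to IkB- for 387 of them (25.2%), and the median gene kept 75.7% of its log2 difference. Of 1010 genes at least 2-fold lower in IkB-, 342 (33.9%) lay nearer to WT and the median gene kept 66.8%. On the yeast scale the genes were chosen anew at 2-fold on that scale, so they are other sets. The shares nearer to WT were then 99.7% for higher and 10.6% for lower genes. Relative to the median gene, 953 genes were at least 2-fold higher in both comparisons with WT, where independent lists would share 148 and simulated libraries that differed by counting error only shared 0.250 on average. For lower genes the overlap was 513, where independent lists would share 67.3 and the simulated libraries shared 0. The number for independent lists ignores that both comparisons use the same WT library, and the simulation holds no difference between animals or preparations, so part of the excess may come from the shared WT.

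**Figure D3:**
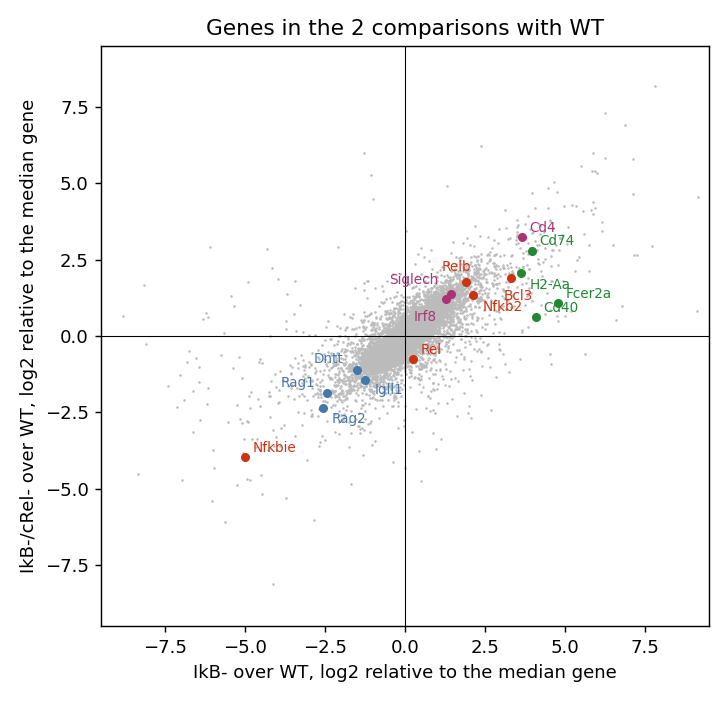
Each point is a gene, placed by its log2 ratio relative to the median gene in IkB- over WT (x axis) and in IkB-/cRel- over WT (y axis), with named genes in colour (red NFkB family, blue V(D)J recombination and Igll1, green later B cell genes, purple Siglech, Irf8 and Cd4). Rag1 and Rag2 lie below 0 on both axes here and on the yeast scale, and Cd40 is at 4.11 and 0.62, the latter -1.05 on the yeast scale.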

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

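All alternatives were listed before the data were examined, and none was added. No paired analysis was possible because each genotype had 1 library, and no library could be left out for the same reason. Depth limits IkB-/cRel- most, with 9351681 mouse counts, and no value has a replicate check. The direction of the mouse per yeast folds did not change under any other total, and the values below moved only past their narrow counting intervals. IkB- over WT, IkB-/cRel- over WT and IkB-/cRel- over IkB- are given in this order throughout. Without the 10 most abundant yeast genes the first and last folds were 2.3835 and 0.12679. By the median over yeast genes the folds were 2.3263, 0.29004 and 0.12438. Without the 10 most abundant mouse genes they were 2.3705, 0.30065 and 0.12683, and without mitochondrial genes 2.4078, 0.30553 and 0.12689. Without immunoglobulin genes the last 2 were 0.30186 and 0.12707. Leaving out yeast ribosomal RNA and mitochondrial genes kept every fold within its counting interval.

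Numbers of genes at least 2-fold higher and lower on the yeast scale became, with scaling by total mouse counts, 1658 and 908, 1341 and 741 and then 422 and 622. With TMM they were 1578 and 986, 1227 and 841 and then 414 and 630, and with DESeq2 size factors of mouse genes 1612 and 952, 1204 and 870 and then 389 and 670, because these scalings remove the common shift. DESeq2 size factors of yeast genes moved none of these numbers by over 1.5 times. A count minimum of 30 gave 404 lower in IkB-, and 259 and 76 higher in IkB-/cRel- over WT and over IkB-, and a minimum of 1000 gave 48, 21 and 4, as more or fewer genes are compared. With the whole interval beyond 2-fold, 46 genes were higher in IkB-/cRel- than in WT.

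Relative to the median gene, a count minimum of 30 gave 1651 and 1522 lower genes over WT, and 961 higher and 1289 lower over IkB-. A minimum of 1000 gave 797 and 366, 591 and 278, and 79 and 163. With the whole interval beyond 2-fold, 669 were lower in IkB-, 713 higher and 351 lower in IkB-/cRel- over WT, and 222 higher and 278 lower over IkB-. A pseudocount of 10 gave 337 lower over IkB-. Centring by TMM moved none of these numbers by over 1.5 times.

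On the yeast scale 29 of the list medians outside the middle 95% of random lists changed sign, since all genes shift by 1 factor. In IkB- over WT these were proteasome 20S core 0.89, cytosolic ribosomal proteins 0.64, mitochondrial ribosomal proteins 0.90, ribosome biogenesis 1.03, cytosolic chaperones and heat shock 0.60, DNA replication 0.69, mitosis 0.46, B lineage transcription factors 0.95, pro-B surface and pre-BCR genes 0.78, V(D)J recombination 0.38, nuclear oxidative phosphorylation 0.88. In IkB-/cRel- over WT they were NFkB family and inhibitors -1.12, NFkB target genes -1.26, later B cell genes -1.05, monocyte and macrophage markers -0.58, T cell markers -0.97, NK and innate lymphoid markers -0.37, dendritic cell markers -0.56, megakaryocyte and platelet markers -0.18, stromal and endothelial markers -0.31, and in IkB-/cRel- over IkB- ribosome biogenesis -2.79, mTORC1 and growth regulators -2.76, DNA replication -2.68, mitosis -2.79, cell cycle regulators -2.78, immediate early genes -2.79, monocyte and macrophage markers -2.67, NK and innate lymphoid markers -2.31, dendritic cell markers -2.65. Lists with a median at least 1.5-fold higher and lower were 40 and 1, 0 and 38, and 0 and 43 on this scale. Named genes at least 2-fold from the median gene that changed sign were Nfkbib at 0.10, Igll1 at 0.058 and Pcna at 0.26 in IkB-, Nfkb2 at -0.33, Cd44 at -0.62, Irf8 at -0.46 and Siglech at -0.30 in IkB-/cRel- over WT, and Nfkbie at -1.94 over IkB-. With genes also chosen on the yeast scale, the share nearer to WT became 99.7% for genes higher and 10.6% for genes lower in IkB-. The median difference kept was -92.6% and 158% in these other sets of genes.

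Selecting genes at 1.5-fold gave 25.8% of lower genes nearer to WT and 75.8% kept, and the cause was not tested. With a count minimum of 1000, with fewer members measured, the median became 0.015 for progenitor genes and 0.75 for plasma cell markers in IkB-/cRel- over IkB-, and -0.069 for monocyte markers in IkB- over WT, and 2 lists had a median at least 1.5-fold higher in IkB-/cRel- than in IkB-. The mean over members gave 0.85 for plasma cell markers and 5 lists with a value at least 1.5-fold lower in that comparison, and the cause was not tested. A count minimum of 30 and a pseudocount of 10 changed the sign of none of these list medians. The pseudocount moved 57 of the 160 named gene values past their counting intervals, 49 of them toward 0 and none past it, and 5 list medians by over 0.5 times their quartile range.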

Other observations

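The immunoglobulin, Ifi200 cluster and single-gene values of the next 2 paragraphs, all tests on mouse counts per yeast count, the neutrophil, erythroid and platelet test and both tests on pro-B genes were chosen after the results were seen.

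Immunoglobulin constant genes went different ways in the 3 libraries. Igha stood at 135 CPM in WT, 0.491 in IkB- and 446 in IkB-/cRel-, Ighg1 at 85.5, 5.02 and 0.321, Ighg2c at 26.9, 3.88 and 0.428, Ighg2b, the most abundant IgG gene, at 238, 236 and 309, Ighg3 at 3.36, 6.69 and 2.35, and Jchain at 93.5, 7.34 and 138. Ighm differed little, at 3419, 3066 and 3450, and Igkc stood at 420, 624 and 781. Heavy chain variable genes summed to 258, 46.4 and 212 CPM in WT, IkB- and IkB-/cRel-. The distal Ighv1 family took 47.6% of these counts in WT (46.4 to 48.9), 68.7% in IkB- (66.7 to 70.7) and 54.7% in IkB-/cRel- (52.5 to 56.9), the proximal Ighv5 family 8.82%, 9.96% and 13.4%, and the proximal Ighv2 family 2.89%, 3.18% and 6.60%. Genes of the Ifi200 cluster on chromosome 1 went opposite ways in IkB-/cRel-: Ifi206 stood at 20.5, 8.37 and 2.67 CPM in WT, IkB- and IkB-/cRel-, Ifi208 at 17.1, 4.33 and 2.57, and Ifi204 at 1.29, 0.669 and 30.0. The mitochondrially encoded mt-Nd3 stood at 1.17, 1.27 and 4.49.

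The gene lists not described in the report are given here by their medians relative to the median gene in IkB- over WT, IkB-/cRel- over WT and IkB-/cRel- over IkB-, and on the yeast scale all of them were above 0 in the first comparison and below 0 in the other 2. Among lists of protein homeostasis, proteasome assembly genes were at -0.25, -0.32 and -0.11, ubiquitin and p97 genes at -0.11, -0.05 and 0.02, the integrated stress response at 0.00, -0.11 and 0.01, autophagy and lysosome genes at 0.07, 0.10 and -0.01, translation factors at -0.21, -0.20 and 0.03, tRNA synthetases at -0.12, -0.13 and -0.04, and ribosome biogenesis genes at -0.26 and -0.09 over WT. Among lists of growth and survival, mTORC1 and growth regulators were at -0.20, 0.00 and 0.21, cell cycle regulators at -0.24, -0.14 and 0.19, IL7 and STAT5 signalling at 0.38, 0.21 and -0.14, survival and apoptosis genes at 0.08, 0.00 and -0.04, p53 targets at -0.10, -0.14 and 0.01, and immediate early genes at -0.25, 0.08 and 0.18. Glycolysis genes were at 0.06, 0.09 and 0.06, nuclear genes of oxidative phosphorylation at -0.42, -0.45 and -0.03, mitochondrially encoded genes at -0.48, -0.40 and 0.07, and the interferon response at 0.00 and -0.11 over WT. B lineage transcription factors were at -0.35, -0.04 and 0.04, and multipotent and lymphoid progenitor genes at 0.40, 0.35 and -0.20. Pro-B genes were at 0.03 in IkB-/cRel- over IkB-, and mitochondrial ribosomal protein genes at 0.00 and cytosolic ones at -0.15. The 19S cap was at -0.19 and endoplasmic reticulum chaperones at 0.16 in IkB-/cRel- over WT. Among markers of other cells, T cell markers were at 0.15, 0.70 and 0.08. Cd4 (49.5, 655 and 489 CPM in WT, IkB- and IkB-/cRel-) held most counts of that list in IkB- and IkB-/cRel-. The T cell list summed to 209, 871 and 736 CPM, and in IkB- over WT 8 of 16 members were above 0 and 8 below. Megakaryocyte and platelet markers were at 1.94, 1.49 and -0.45 (Itgb3 at 23.3, 108 and 98.7 CPM). Basophil and mast cell markers were at 0.59, 0.09 and -0.57 (Prss34 at 11.0, 26.0 and 17.5). Stromal and endothelial markers were at 0.94, 1.37 and 0.31 (Pecam1 at 187, 231 and 258). Monocyte and macrophage markers were at 1.10 and 0.30, erythroid markers at 0.05, plasma cell markers at 0.40 and -0.25 (in both, 3 of 8 higher and 3 lower, the latter median turning to 0.75 at a count minimum of 1000 and the mean being 0.85), dendritic cell markers at 0.32 and NK and innate lymphoid markers at 0.49 in the comparisons where the report does not give them. The member with the highest count was Mpo for neutrophils, at 92.1, 197 and 160 CPM in WT, IkB- and IkB-/cRel-, Ly6c2 for monocytes, at 184, 307 and 415, Tfrc for erythroid cells, at 403, 684 and 682, Klrd1 for NK cells, at 48.3, 101 and 131, and Txndc5 for plasma cells, at 141, 283 and 247.

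The first pattern weighed is the difference in mouse counts per yeast count. A few yeast genes do not set the scale, since 98.8% of 6035 yeast genes taken alone gave over 1.5-fold for IkB- over WT, nor do a few mouse genes, the median mouse gene being 2.45-fold higher. A constant share of yeast reads counted at mouse genes adds the same amount to every ratio, so it is not the cause of the 3.31-fold of WT over IkB-/cRel-, and a share that differs between libraries was not tested. An unequal number of cells, RNA yield or amount of yeast RNA gives the same 2.37-fold as more RNA per cell, and these cannot be told apart with 1 library per genotype.

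The second pattern is a set of 92 genes at least 4-fold higher in IkB- than in WT, at least 2-fold lower in IkB-/cRel- than in IkB- and under 2-fold higher than WT there, thresholds chosen after the data were seen, with medians of 2.58 for IkB- over WT, 0.30 for IkB-/cRel- over WT (below 0 on the yeast scale) and -2.51 for IkB-/cRel- over IkB-. Mature B cells in IkB- may add to it: Ighd, Igkc, Ms4a1 and Cd22 had a median of -0.03 (-0.0268), under the bound of 0.5 set before, but that bound was wrong, since these markers had a median of 79.1 CPM in WT against 8.01 for the pattern's genes in IkB-, and Cr2, under the count minimum, had 2, 69 and 1 counts. Mature dendritic cells may add to it as well, with a median of 1.15 over 6 measured markers (Cst3 at 255 and 222 CPM in WT and IkB-, Itgax at 70.4 and 142), between the bounds set before, and neither source can be told apart from a change within the progenitors. Zbtb46, the highest of these 6 dendritic markers at 2.29, belongs to the 92 genes itself, so it was chosen for being higher. RNA of neutrophils, erythroid cells or platelets stays open for all 92 genes, 8 of them members of those lists: the summed excess over WT of the other 84 was 2.75 times that of the lists (1775 against 644 CPM), but the genes were chosen for their excess and 4 of them made up 43.8% of it, and this ratio had replaced a first bound of 1% of mouse counts (0.224% for the pattern, 0.142% for the lists) after the data were seen. Of the 92 genes, 3 lay within 10 Mb of Nfkbia, Nfkbib, Nfkbie or Rel. That was 0.909 times the share of all genes (0.189 to 2.58, an interval condition added after the value was seen). This share cannot decide whether DNA of another strain around those genes plays a part. The set left out genes that stayed high in IkB-/cRel-, whose label holds IkB- too, and DNA elsewhere was not tested.

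In the third pattern, Rag1, Rag2 and 6 pro-B identity genes were lower relative to the median gene in both IkB- and IkB-/cRel-. Most genes of plasmacytoid dendritic cells were higher in both. On the yeast scale 5 of the 6 identity genes were above 0 in IkB- and most of the dendritic genes below 0 in IkB-/cRel-. Klk1, a member of the dendritic cell marker list, was among the lowest genes in IkB-/cRel- over WT, though near-identical copies make its value uncertain. A larger share of plasmacytoid dendritic RNA would fit the higher genes: a second list, of which 22 of 24 genes were measured, had medians of 1.41 in IkB- and 1.34 in IkB-/cRel-, with 21 and 22 higher, though 21 were at 1 CPM or more in WT too, 0 were in another list, and Tlr7, whose counts had been seen, was taken out after a first run that gave the same 1.34. Its most abundant genes were Mpeg1, at 1531, 4493 and 4048 CPM, and Plac8, at 896, 933 and 1118, Siglech standing at 825, 2297 and 2211, and the labels do not give the markers of the sort that would remove such cells. Dilution stays open for Rag1 and Rag2 too, which lay below the 6 identity genes (Pax5, Ebf1, Igll1, Vpreb3, Cd79a and Cd79b) by at least 0.277 between counting intervals, less than the range of 1.04 over those genes. The 6 genes had medians of -0.97 and -1.22 and all were lower, with a range above 0.5, a bound set after, so dilution and lower expression cannot be told apart.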
